A study of Homo sapiens with 9 samples.

How the data were processed

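RNA from A549 cells was extracted with TRIzol and made into libraries with a NEBNext Ultra kit, per the labels' protocols, which do not state that the kit keeps the strand. The submitters' processing notes name the human genome build hg38, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 from Subread, and limma, without giving their roles or order. The authors deposited a table of whole-number read counts per gene, not normalized, and a table of FPKM values (fragments scaled by gene length and library total) for the same 62257 gene rows and 9 libraries. Each deposited FPKM value equalled the count divided by gene length and library total, times a factor per library between 0.944 and 1.01 whose origin is not given in the sources used here. Of the rows 61552 carried an Ensembl gene ID and 705 were transcripts named only as not annotated, with 0.313% to 0.357% of the counts, and 61399 IDs matched a gene symbol. Coordinates are those of the deposited tables, and gene types come from GENCODE v29, which may not be the annotation release the authors used.

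Groups and replicate numbers came from the sample titles. The main test was edgeR's quasi-likelihood test with robust settings on the deposited counts (edgeR 4.0.16, R 4.3.3), with TMM scaling, edgeR's default expression filter and all 9 libraries in 1 fit without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed, with no fold minimum. Every adjusted p of a gene comes from that test unless another is named. The SE of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 0.0992. CPM values of genes use TMM-scaled library sizes, while the summed CPM of marker lists uses the unscaled library totals. Group values are mean ± SD over 3 libraries.

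Gene lists, 54 in number, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for named genes. The 47 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of a comparison. The remaining 7 had fewer tested members, and the 6 of these that hold markers of other cell types are given as summed CPM. Each list was also tested with an estimated correlation and with fry. Estimating the correlation weakened calls even where the estimate lay below the preset value. The mesenchymal list with DDP_apoEV, at an estimate of 0.00242, went from an unadjusted camera p of 2.39e-05 to 0.00401. A call lost in this way therefore does not by itself show that the members are correlated. In other called lists the estimate lay far above the preset 0.01. It was 0.657 for ribosomal proteins, 0.469 for mitochondrial-genome transcripts, 0.423 for acute-phase genes and 0.375 for mucin genes. For such lists the preset value understates the estimated correlation. The estimate also lay below the preset value for the histone (−0.0502), MHC class I (−0.0321), apoptosis (−0.0059) and interferon (0.00421) lists. Genes were named by rule. The rule asked for protein-coding genes where a type is given in the deposited tables, and they give none, so non-coding genes could enter. It took the 8 largest rises and 8 largest falls against control (5 and 5 between the vesicle types) among called genes with a symbol, a mean log2 CPM of at least 1 and no overlap between the 3 and 3 libraries. It added up to 4 called members of smallest p from each of up to 8 lists per comparison, among lists called or with at least 3 called members, and 8 fixed genes (CDKN1A, MDM2, MKI67, BCL2L1, CDH1, VIM, GAPDH and ACTB). Some genes the rule took are not reported here. Further list members are given as examples and were chosen after their values were seen. Libraries did not overlap for 32.2%, 43.3% and 47.5% of genes in the 3 comparisons, where chance gives 10%.

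The scripts were tested on simulated counts drawn from the real means and library sizes. For DDP_apoEV against control, 61 of 100 genes changed 1.5-fold and 76 of 100 changed 2-fold were recovered among 16267 genes, and 10.5% of the calls were false. For STS_apoEV against control the numbers were 53, 74 and 7.97% among 16257 genes, and between the vesicle types 59, 78 and 9.87% among 16128 genes, shares of false calls above the nominal level. A list shifted by −0.3 on the log2 scale was called in each simulated comparison and 0 of 46 other lists were. Genes were simulated independently of each other, so this does not show how often camera falsely calls lists whose genes are correlated.

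Alternatives covered median-of-ratios and upper-quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 or no filter, a fold minimum, a replicate block, fits of the compared groups alone, and each library left out in turn. Thinning to equal depth and removing trends on GC content and transcript length were added after seeing the data. GC content and length, from the longest GENCODE v29 transcript, were known for 16156 genes. They were known for at least 88.9% of the tested members of the DNA replication, ribosome biogenesis, ribosomal protein, mitochondrial-genome and histone lists. This share was not computed for the other lists. Replicates of a group differed by more than sampling noise. Ribosomal protein, histone and metallothionein genes, AKR1C1, AKR1C2, AKR1B10, KLRC2, CEACAM6, the HSP90 genes, GAPDH and ACTB have close copies or pseudogenes between which the authors' counting could split reads, and their values are uncertain to that extent. Reads of overlapping antisense genes cannot be told apart without strand.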

Results

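Gene expression was measured by RNA sequencing in A549 cells, an established human lung adenocarcinoma line of epithelial origin. The cells had been treated for 96 h with phosphate-buffered saline or with apoptotic extracellular vesicles (apoEVs), the membrane-bound particles that dying cells shed. One kind of vesicle came from apoptosis induced by cisplatin, a platinum drug that crosslinks DNA, and is called DDP_apoEV here. The other came from apoptosis induced by staurosporine, a broad protein kinase inhibitor, and is called STS_apoEV. The labels do not state which cells shed the vesicles, and no sample of either drug alone was analysed here. Each of the 3 groups held 3 libraries, 9 in all. The total count per library ran from 14356195 to 15492993 in control, from 15949255 to 16526399 in DDP_apoEV and from 13799950 to 14816996 in STS_apoEV. Transcripts of the mitochondrial genome took 11.4% to 12.5% of the counts in control, 12.1% to 13.1% in DDP_apoEV and 12.7% to 13.1% in STS_apoEV. After the filter on low counts 16947 genes were tested, of which 7642 (45.1%) differed among the 3 groups. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

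**Figure D1:**
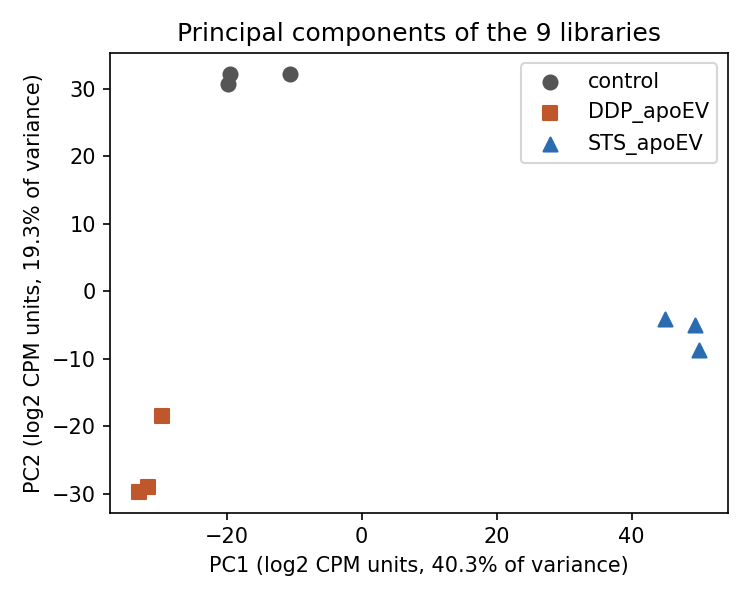
Principal components of log2 CPM over the 16947 tested genes. Each point is a library, the x axis is PC1 (40.3% of the variance) and the y axis is PC2 (19.3%), both in log2 units. The STS_apoEV libraries lie between 44.9 and 50.1 on PC1 and the other libraries at −10.7 or lower.

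The first comparison asked what vesicles from cisplatin-induced apoptosis changed in the cells. KRT4, an epithelial keratin, fell 20.8-fold, from 54.3 ± 4.80 to 2.63 ± 2.63 CPM (counts scaled by library size; SD, n = 3; log2 fold change −4.38, SE 0.493, adjusted p = 0.00164). CEACAM6, a cell-surface adhesion glycoprotein, fell 8.66-fold from 849 ± 50.6 to 98.1 ± 20.2 CPM (adjusted p = 1.26e-11). The neuropeptide precursor gene NTS fell 11.8-fold, the neuropeptide Y receptor gene NPY1R 12.8-fold, the long non-coding RNA LINC01559 9.45-fold and the copper-carrying plasma protein gene CP 7.97-fold. Genes that rose included RNF182 (8.14-fold), the monocarboxylate transporter family gene SLC16A6 (6.75-fold), NPTX1 (5.83-fold), CLMP (4.92-fold) and ABCA1, which exports cholesterol from cells (5.28-fold, from 5.02 ± 0.262 to 26.5 ± 5.50 CPM, adjusted p = 1.68e-13). BMPER rose from 0.378 ± 0.225 to 2.84 ± 0.439 CPM and MYH15 to 3.82 ± 1.58 CPM (log2 fold change 2.44). KRT4 (ENSG00000170477) lies on chromosome 12 at 52806549 to 52814116, minus strand, CEACAM6 (ENSG00000086548) on chromosome 19 at 41750977 to 41772211, plus strand, and ABCA1 (ENSG00000165029) on chromosome 9 at 104781006 to 104928155, minus strand, all protein-coding genes in hg38 coordinates as deposited. In all, 2623 of 16947 genes changed, 1213 higher and 1410 lower, and 560 of them by 2-fold or more, 205 higher and 355 lower. Limma on log2(FPKM + 1), which tested only 12647 genes, called 819 higher and 805 lower. On the log2(FPKM + 1) scale, which understates the change of low genes, ABCA1 moved from 2.40 to 1.20. Leaving out DDP_apoEV replicate 3 moved KRT4 to −5.60 and the drug efflux pump gene ABCB1 from −2.89 to −3.94, and leaving out control replicate 1 moved ANKRD22 from 2.33 to 2.92, all on the log2 scale.

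Several groups of epithelial and secretory genes fell with DDP_apoEV. Of 12 mucin and goblet-cell genes 8 fell, 0 rose and 4 did not pass, with a median log2 fold change of −1.39 (8 fell adjusted over the list alone; camera adjusted p = 4.37e-07, and adjusted p = 0.287 with an estimated correlation). AGR2, a secretory-pathway protein, fell 2.47-fold from 671 ± 25.1 to 272.0 ± 59.2 CPM, and the goblet-cell transcription factor gene SPDEF fell 2.77-fold. Of 15 acute-phase, complement and coagulation genes 8 fell, 1 rose and 6 did not pass (8 fell and 2 rose adjusted over the list alone; adjusted p = 0.00124, and adjusted p = 0.486 with an estimated correlation). FGG, a fibrinogen chain gene, fell 7.77-fold, and C1S, a complement protease gene, rose (log2 fold change 0.44). Serum albumin and hepatocyte markers summed to 39.9 ± 0.923 CPM in control, 13.6 ± 2.72 with DDP_apoEV and 34.4 ± 1.51 with STS_apoEV (SD, n = 3), and FGL1 held 93.1% of them. Of 18 epithelial identity genes 6 fell, 1 rose and 11 did not pass (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.00216, and adjusted p = 0.362 with an estimated correlation). The keratin genes KRT8 and KRT18 fell, each by 0.83 on the log2 scale, and CLDN1, a tight junction gene, rose by 0.50. CDH1, the E-cadherin gene, fell from 17.4 ± 2.15 to 11.2 ± 3.29 CPM (log2 fold change −0.63, SE 0.171, adjusted p = 0.0122). The CDH1 call was lost without control replicate 3 (adjusted p = 0.0712), without DDP_apoEV replicate 1 (0.0846) and with limma on log2(FPKM + 1) (0.0743).

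Genes of the mesenchymal list moved the other way. Of 21 members 8 rose, 0 fell and 13 did not pass, with a median log2 fold change of 0.45 (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.88e-04, and adjusted p = 0.167 with an estimated correlation). The intermediate filament gene VIM rose 1.44-fold, from 309 ± 19.7 to 446 ± 39.6 CPM. The transcription factor gene ZEB2 rose 1.89-fold and the integrin gene ITGA5 1.71-fold. With STS_apoEV the mesenchymal median was 0.475 (6 rose and 3 fell) and the epithelial median −0.448 (6 fell and 3 rose). Camera called neither list there (adjusted p = 0.2 and 0.196) or between the vesicle types (0.294 and 0.495). Fry called the mesenchymal list lower (adjusted p = 0.00123) and the epithelial list higher (0.0143) with STS_apoEV than with DDP_apoEV.

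Metabolic and growth gene groups also changed with DDP_apoEV. Of 25 cholesterol synthesis and uptake genes 15 fell, 0 rose and 10 did not pass (18 fell adjusted over the list alone; adjusted p = 7.77e-08, and adjusted p = 0.201 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell 1.63-fold from 486 ± 46.8 to 299 ± 8.57 CPM. Of 30 targets of NRF2, the oxidative stress transcription factor, 14 fell, 0 rose and 16 did not pass (16 fell and 1 rose adjusted over the list alone; adjusted p = 8.26e-04, and adjusted p = 0.201 with an estimated correlation). GPX2, a glutathione peroxidase gene, fell 2.17-fold from 1357 ± 122 to 626 ± 112 CPM. Of 30 ribosome biogenesis and MYC target genes 20 rose, 0 fell and 10 did not pass, with a median of 0.31 (22 rose adjusted over the list alone; adjusted p = 1.04e-09, and adjusted p = 0.167 with an estimated correlation). The nucleolar protein gene NOLC1 and the polyamine synthesis gene ODC1 rose 1.46-fold and 1.47-fold. Of 31 DNA replication genes 12 rose, 0 fell and 19 did not pass, with a median of 0.19 (14 rose adjusted over the list alone; adjusted p = 5.1e-06, and adjusted p = 0.167 with an estimated correlation), and the replication factor gene MCM10 rose 1.33-fold.

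The remaining list calls, some of them less stable, completed the DDP_apoEV comparison. Of 15 drug efflux and platinum transport genes 6 fell and 1 rose (6 fell and 1 rose adjusted over the list alone; adjusted p = 0.0234, and adjusted p = 0.362 with an estimated correlation), ABCB1 by 7.40-fold from 3.90 ± 1.05 to 0.524 ± 0.497 CPM. The list was not called without control replicate 3 (0.0512) or without DDP_apoEV replicate 1 (0.0629). Of 30 mitosis genes 8 fell and 1 rose, with a median of −0.10 (9 fell and 1 rose adjusted over the list alone; adjusted p = 0.0486, and adjusted p = 0.579 with an estimated correlation). It was not called without control replicate 1 (0.114), control replicate 2 (0.113), DDP_apoEV replicate 2 (0.110) or DDP_apoEV replicate 3 (0.0942), nor with median-of-ratios size factors (0.0592) or fry (0.0584). The proliferation marker gene MKI67 stood at 250.0 ± 24.4 CPM against 249.7 ± 14.9 in control (adjusted p = 0.990), with a sign that turned with upper-quartile factors. Of 45 cytosolic ribosomal protein genes 19 rose and 0 fell (25 rose adjusted over the list alone; adjusted p = 9.66e-08, and adjusted p = 0.540 with an estimated correlation), RPL27 by 1.32-fold, and fry did not call the list (adjusted p = 0.0586). Of 5 metallothionein-list genes 2 rose (3 rose adjusted over the list alone; adjusted p = 0.00982, and adjusted p = 0.344 with an estimated correlation), of which MT2A rose by 1.51 on the log2 scale. Signs of RNA composition moved with the treatment too, since 3 of 13 mitochondrial-genome transcripts rose (4 rose adjusted over the list alone; adjusted p = 0.00536, and adjusted p = 0.540 with an estimated correlation) and 4 of 9 replication-dependent histone genes rose (5 rose adjusted over the list alone; adjusted p = 8.73e-04, and adjusted p = 0.167 with an estimated correlation).

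Among the 8 genes fixed beforehand, CDKN1A, a p53 target that restrains the cell cycle, fell from 65.4 ± 2.25 to 54.3 ± 6.53 CPM with DDP_apoEV (log2 fold change −0.27, adjusted p = 0.0305). The survival gene BCL2L1 rose by 0.24 (adjusted p = 0.0264) and GAPDH, a glycolytic enzyme gene, by 0.24 (adjusted p = 0.0168). MDM2, another p53 target, had a log2 fold change of −0.18 (adjusted p = 0.123). CDKN1A was not called without control replicate 1 (0.0945), control replicate 3 (0.101), DDP_apoEV replicate 1 (0.178) or DDP_apoEV replicate 3 (0.140), or with limma on log2(FPKM + 1) (0.0794), BCL2L1 not without control replicate 2 (0.184), DDP_apoEV replicate 1 (0.106) or DDP_apoEV replicate 2 (0.0764), and GAPDH not without control replicate 2 (0.0784), control replicate 3 (0.0715) or DDP_apoEV replicate 2 (0.0868). Of the 47 lists tested 14 were called, 7 higher and 7 lower, and 0 held with an estimated correlation. A fit of these 6 libraries alone called 15 lists, and other splits of the same 6 libraries called up to 9.

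The second comparison asked the same of vesicles from staurosporine-induced apoptosis. ANKRD1, a target of the mechanically regulated coactivators YAP and TAZ, fell from 50.4 ± 8.31 to 1.32 ± 0.480 CPM (log2 fold change −5.25, SE 0.185, adjusted p = 1.57e-18), CCN2, a matricellular growth factor gene, 9.80-fold from 34.3 ± 0.839 to 3.49 ± 0.286 CPM, and CCN1 6.90-fold and AMOTL2 4.51-fold, all targets of the same coactivators. KRT4, C1orf116, GFRA1, MYPN and ATP10A fell between 8.29-fold and 16.4-fold. The angiotensin receptor gene AGTR1 rose 16.1-fold from 0.727 ± 0.342 to 11.8 ± 0.566 CPM, SLC16A6 18.2-fold from 3.58 ± 0.749 to 64.9 ± 5.21 CPM, CHST2 9.88-fold, the laminin gene LAMA4 8.89-fold, BAIAP3 8.51-fold and SCG2 8.37-fold. ANKRD1 (ENSG00000148677) lies on chromosome 10 at 90912096 to 90921087, minus strand, CCN2 (ENSG00000118523) on chromosome 6 at 131948176 to 131951372, minus strand, and SLC16A6 (ENSG00000108932) on chromosome 17 at 68267026 to 68291267, minus strand, all protein-coding. In all, 5552 genes changed, 2698 higher and 2854 lower, a balance that turned with upper-quartile factors (2977 higher and 2596 lower). At 2-fold or more there were 1130, of which 699 were higher and 431 lower. On the log2(FPKM + 1) scale AGTR1 moved from 4.01 to 1.84. Leaving out STS_apoEV replicate 1 moved GFRA1 from −3.27 to −3.89.

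Cell-cycle genes fell with STS_apoEV. Of 31 DNA replication genes 24 fell, 0 rose and 7 did not pass, with a median log2 fold change of −0.63 (24 fell and 1 rose adjusted over the list alone; camera adjusted p = 3.65e-13, and adjusted p = 0.0471 with an estimated correlation). MCM10 fell 2.48-fold, from 68.6 ± 4.40 to 27.6 ± 0.395 CPM, UHRF1 2.39-fold, CDC6 1.87-fold and MCM6 1.64-fold. Of 30 mitosis genes 26 fell, 0 rose and 4 did not pass (26 fell adjusted over the list alone; adjusted p = 5.47e-11, and adjusted p = 0.0960 with an estimated correlation). The spindle gene TPX2 fell 1.61-fold, and MKI67 fell 1.51-fold, from 249.7 ± 14.9 to 165 ± 11.1 CPM. Of 25 DNA damage recognition and repair genes 16 fell and 1 rose (17 fell and 1 rose adjusted over the list alone; adjusted p = 7.74e-06, and adjusted p = 0.0854 with an estimated correlation), among them the mismatch repair gene MSH6 (1.75-fold) and the Fanconi anaemia gene FANCD2 (1.78-fold). Of 30 ribosome biogenesis and MYC target genes 18 fell and 1 rose (22 fell and 1 rose adjusted over the list alone; adjusted p = 2.35e-05, and adjusted p = 0.194 with an estimated correlation). CDKN1A rose 1.36-fold to 88.9 ± 5.02 CPM (adjusted p = 1.07e-04) and MDM2 1.29-fold (adjusted p = 2.47e-04). BCL2L1 fell 1.42-fold (adjusted p = 5.46e-06).

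Of 23 YAP and TAZ targets 15 fell, 2 rose and 6 did not pass, with a median of −0.67 (15 fell and 3 rose adjusted over the list alone; adjusted p = 2.57e-08, and adjusted p = 0.0802 with an estimated correlation). With DDP_apoEV 7 of these targets fell and 5 rose. Camera did not call the list there (adjusted p = 0.361), while fry called it lower (adjusted p = 0.0299). Of 21 cytoskeleton and SRF targets 11 fell and 1 rose (11 fell and 3 rose adjusted over the list alone; adjusted p = 7.62e-04, and adjusted p = 0.127 with an estimated correlation), and the actin gene ACTB fell 1.62-fold, from 1859 ± 125 to 1149 ± 65.5 CPM. The lowest log2 fold change in the SRF list, −3.29, equalled that of CCN2. The SRF list and the YAP and TAZ list may therefore share members and not be separate results. CDH1 fell 1.88-fold. VIM rose 1.22-fold (adjusted p = 0.00274), a call lost without control replicate 2 (0.0504), and GAPDH had a log2 fold change of 0.00 (adjusted p = 0.972), with a sign that turned with upper-quartile factors. Of 17 heat shock genes 14 fell and 1 rose (14 fell and 1 rose adjusted over the list alone; adjusted p = 1.15e-07, and adjusted p = 0.0960 with an estimated correlation). HSP90AA1, a stress-inducible chaperone gene, fell 2.02-fold, from 3605 ± 129 to 1781 ± 160.0 CPM, and FKBP4 2.18-fold. Of 25 cholesterol synthesis and uptake genes 14 fell and 1 rose (14 fell and 1 rose adjusted over the list alone; adjusted p = 2.74e-04, and adjusted p = 0.266 with an estimated correlation). Of 17 fatty acid synthesis genes 9 fell and 2 rose (10 fell and 2 rose adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.457 with an estimated correlation). Of 29 ATF4 stress response genes 14 fell and 5 rose (15 fell and 5 rose adjusted over the list alone; adjusted p = 0.0439, and adjusted p = 0.467 with an estimated correlation), a list not called without control replicate 1 (0.0821), STS_apoEV replicate 1 (0.0608) or STS_apoEV replicate 3 (0.0598), nor with the CPM filter (0.0559).

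Inflammatory and lysosomal genes rose with STS_apoEV. Of 25 NF-kB inflammatory genes 20 rose, 1 fell and 4 did not pass, with a median of 0.92 (21 rose and 1 fell adjusted over the list alone; adjusted p = 2.72e-10, and adjusted p = 0.0802 with an estimated correlation). The neutrophil chemokine gene CXCL5 rose 1.90-fold, from 570.1 ± 60.2 to 1080.0 ± 82.6 CPM, CXCL3 2.23-fold and the NF-kB subunit gene RELB 2.65-fold. The list of senescence-associated secreted factors, which shares chemokine and interleukin genes with that list, had 13 of 17 genes higher and 2 lower (13 rose and 2 fell adjusted over the list alone; adjusted p = 4.52e-05, and adjusted p = 0.0971 with an estimated correlation). Of 29 interferon-stimulated genes 16 rose, 2 fell and 11 did not pass (19 rose and 2 fell adjusted over the list alone; adjusted p = 7.74e-06, and adjusted p = 0.0471 with an estimated correlation). IFIT3 rose 2.81-fold and ISG15 2.68-fold, while OAS3 and USP18 fell. Of 9 antigen presentation genes of MHC class I 7 rose and 1 fell (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.00181, and adjusted p = 0.0802 with an estimated correlation), B2M by 0.85 on the log2 scale. Of 29 lysosome and autophagy genes 16 rose and 0 fell (16 rose adjusted over the list alone; adjusted p = 1.36e-05, and adjusted p = 0.273 with an estimated correlation), with WIPI1, an autophagosome gene, up 2.86-fold and the cathepsin gene CTSB 1.87-fold. Counts of macrophage and monocyte markers summed to 23.9 ± 2.75 CPM with STS_apoEV, 13.4 ± 3.21 in control and 15 ± 0.916 with DDP_apoEV (SD, n = 3), and CD14 held 70.4% of them.

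Other lists were called higher with STS_apoEV. Of 18 matrix metalloproteinase and invasion genes 11 rose and 2 fell (11 rose and 2 fell adjusted over the list alone; adjusted p = 0.00124, and adjusted p = 0.127 with an estimated correlation), and of 30 apoptosis regulators 14 rose and 4 fell (17 rose and 5 fell adjusted over the list alone; adjusted p = 0.00428, and adjusted p = 0.0802 with an estimated correlation). Of 45 cytosolic ribosomal protein genes 17 rose and 0 fell (17 rose adjusted over the list alone; adjusted p = 0.00145, and adjusted p = 0.714 with an estimated correlation), a list fry did not call (adjusted p = 0.117), and of 9 replication-dependent histone genes 6 rose (6 rose adjusted over the list alone; adjusted p = 0.00130, and adjusted p = 0.0802 with an estimated correlation). Of 13 mitochondrial-genome transcripts 6 rose (8 rose adjusted over the list alone; adjusted p = 0.0233, and adjusted p = 0.585 with an estimated correlation), a call lost without control replicate 1 (0.103) or STS_apoEV replicate 3 (0.0803). The metallothionein list had 2 of 5 genes higher (3 rose adjusted over the list alone; adjusted p = 0.0310, and adjusted p = 0.273 with an estimated correlation), a call lost without control replicate 3 (0.0532) or STS_apoEV replicate 2 (0.0574). In all 21 of 47 lists were called, 11 higher and 10 lower, and 2 held with an estimated correlation. Other splits of these 6 libraries called up to 10 lists.

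**Figure D2:**
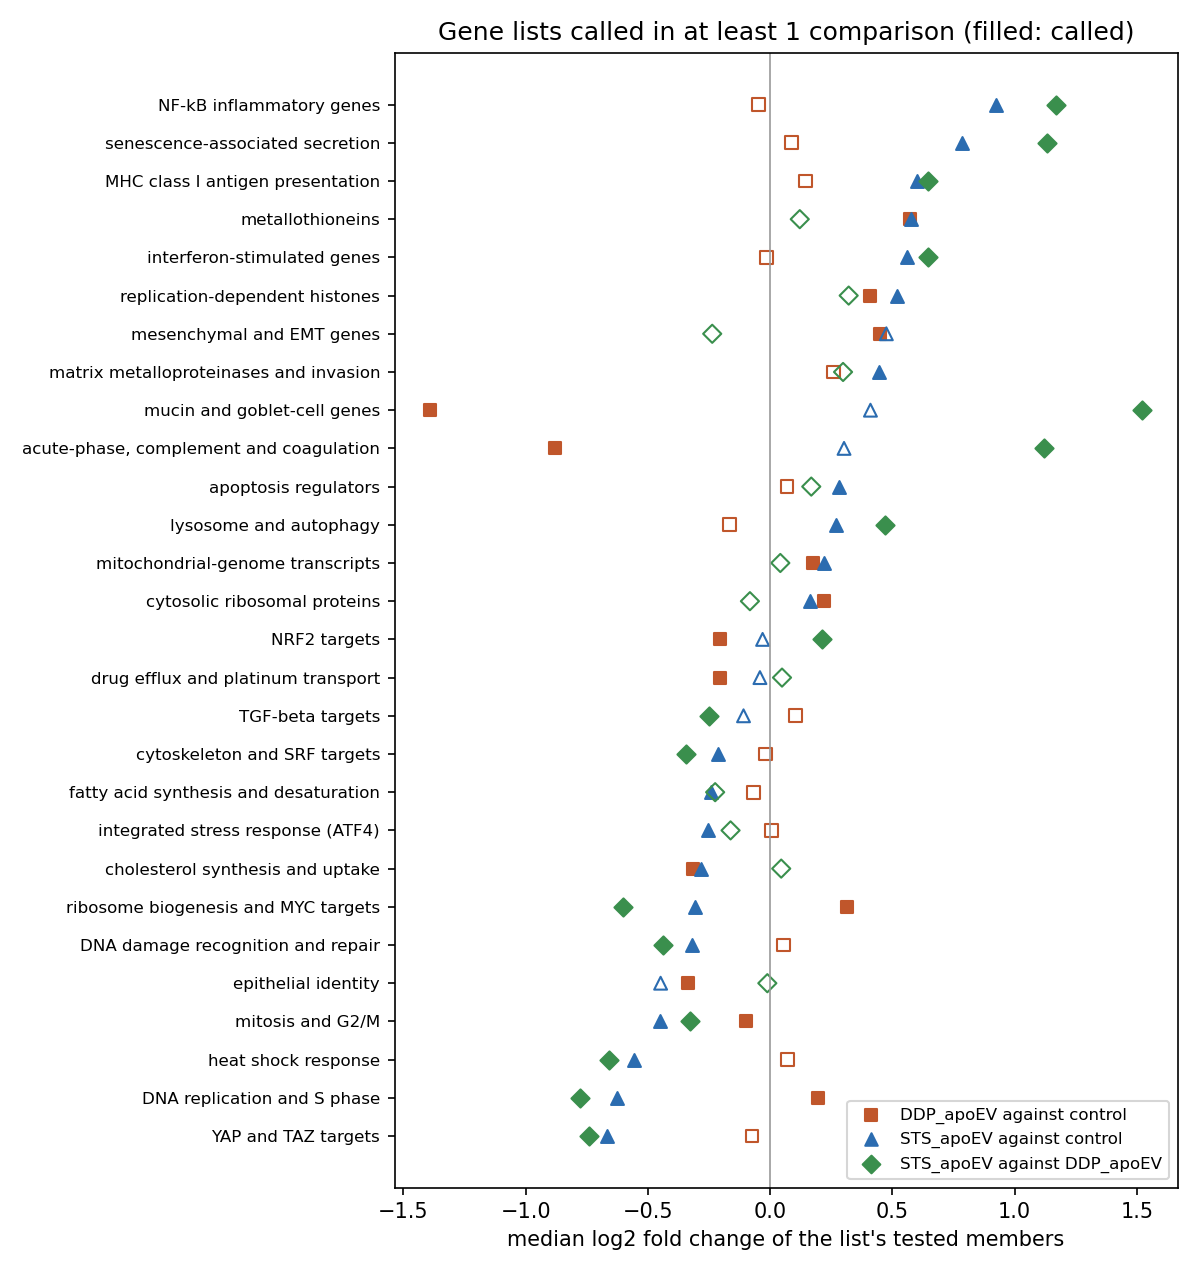
Median log2 fold change of the tested members of each gene list (x axis) for the lists called in at least 1 comparison (y axis), with squares for DDP_apoEV against control, triangles for STS_apoEV against control and diamonds for STS_apoEV against DDP_apoEV. Filled symbols are called by camera with its preset correlation. DNA replication lies at 0.19 with DDP_apoEV and −0.63 with STS_apoEV.

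The third comparison set the vesicle types against each other, which is also the test of whether their effects against control differ. The coagulation factor gene F5 was 21.2-fold higher (33.6 ± 2.72 against 1.58 ± 0.551 CPM, adjusted p = 1.02e-18), TPPP3 26.8-fold, CP 17.0-fold and the vitamin B12-binding protein gene TCN1 16.5-fold higher. KLRC2, a gene of the natural killer receptor family, was 14.1-fold higher. NPTX1 was 11.6-fold lower with STS_apoEV, ANKRD1 9.86-fold, HPDL 9.05-fold and GFRA1 13.5-fold lower. TPPP3 (ENSG00000159713) lies on chromosome 16 at 67389809 to 67393518, minus strand, and F5 (ENSG00000198734) on chromosome 1 at 169511951 to 169586588, minus strand, as protein-coding genes. In all, 6721 genes differed, 3422 higher and 3299 lower with STS_apoEV. This balance turned with median-of-ratios factors (3292 higher and 3429 lower), without DDP_apoEV replicate 2 (2935 and 3042) and without STS_apoEV replicate 1 (2889 and 2967), among other alternatives. Of the 1481 that differed by 2-fold or more 1007 were higher and 474 lower. On the log2(FPKM + 1) scale F5 moved from 4.41 to 1.95. Leaving out STS_apoEV replicate 1 moved GFRA1 from −3.75 to −4.38.

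Of 31 DNA replication genes 29 were lower with STS_apoEV than with DDP_apoEV, 0 were higher and 2 did not pass, with a median of −0.78 (30 lower adjusted over the list alone; adjusted p = 4.11e-16, and adjusted p = 0.0397 with an estimated correlation). Of 30 ribosome biogenesis genes 25 were lower and 1 higher (25 lower and 1 higher adjusted over the list alone; adjusted p = 9.96e-11, and adjusted p = 0.115 with an estimated correlation), NOLC1 by 2.19-fold and NOP56 by 1.75-fold. Of 23 YAP and TAZ targets 17 were lower and 2 higher (17 lower and 3 higher adjusted over the list alone; adjusted p = 3.01e-07, and adjusted p = 0.115 with an estimated correlation), WWC1 by 4.03-fold and the receptor kinase gene AXL by 3.04-fold. Of 12 mucin and goblet-cell genes 10 were higher and 0 lower (10 higher adjusted over the list alone; adjusted p = 2.19e-05, and adjusted p = 0.223 with an estimated correlation), and of 15 acute-phase genes 10 were higher and 2 lower (10 higher and 2 lower adjusted over the list alone; adjusted p = 3.37e-04, and adjusted p = 0.381 with an estimated correlation). Of 25 NF-kB genes 19 were higher and 3 lower (19 higher and 3 lower adjusted over the list alone; adjusted p = 9.34e-07, and adjusted p = 0.136 with an estimated correlation), CXCL2 by 2.47-fold and CCL2 by 2.19-fold. Of 30 NRF2 targets 16 were higher and 1 lower (18 higher and 1 lower adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.221 with an estimated correlation), and of 29 interferon-stimulated genes 19 were higher and 3 lower (19 higher and 3 lower adjusted over the list alone; adjusted p = 7.81e-05, and adjusted p = 0.0881 with an estimated correlation). Of 29 lysosome and autophagy genes 22 were higher and 1 lower (24 higher and 1 lower adjusted over the list alone; adjusted p = 1.00e-06, and adjusted p = 0.223 with an estimated correlation). The TGF-beta target list, 12 lower and 7 higher of 23 (13 lower and 7 higher adjusted over the list alone; adjusted p = 0.0276, and adjusted p = 0.313 with an estimated correlation), was not called without DDP_apoEV replicate 2 (0.0565).

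Of 30 mitosis genes 23 were lower and 0 higher (24 lower adjusted over the list alone; adjusted p = 3.01e-07, and adjusted p = 0.189 with an estimated correlation), and of 17 heat shock genes 14 were lower and 2 higher (14 lower and 2 higher adjusted over the list alone; adjusted p = 2.87e-06, and adjusted p = 0.171 with an estimated correlation). Of 25 DNA repair genes 18 were lower and 2 higher (18 lower and 2 higher adjusted over the list alone; adjusted p = 2.29e-06, and adjusted p = 0.115 with an estimated correlation), and of 21 cytoskeleton and SRF targets 12 were lower and 2 higher (14 lower and 2 higher adjusted over the list alone; adjusted p = 7.21e-05, and adjusted p = 0.136 with an estimated correlation). Of 17 senescence-associated secreted factors 12 were higher and 3 lower (13 higher and 3 lower adjusted over the list alone; adjusted p = 5.35e-04, and adjusted p = 0.189 with an estimated correlation), and of 9 MHC class I genes 5 were higher and 0 lower (5 higher adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.136 with an estimated correlation). The cholesterol synthesis list was not called between the vesicle types, with 8 of 25 higher and 4 lower with STS_apoEV (8 higher and 4 lower adjusted over the list alone; adjusted p = 0.691). CDH1 had a log2 difference of −0.27 (adjusted p = 0.241), a difference that passed without DDP_apoEV replicate 1 (adjusted p = 0.0180). VIM was lower with STS_apoEV by 0.24 on the log2 scale (adjusted p = 0.0117), a call lost without DDP_apoEV replicate 1 (0.0529), DDP_apoEV replicate 2 (0.0589) or STS_apoEV replicate 1 (0.0554). In all 16 of 47 lists were called, 8 higher and 8 lower, and 1 held with an estimated correlation. Other splits of these 6 libraries called up to 15 lists.

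**Figure D3:**
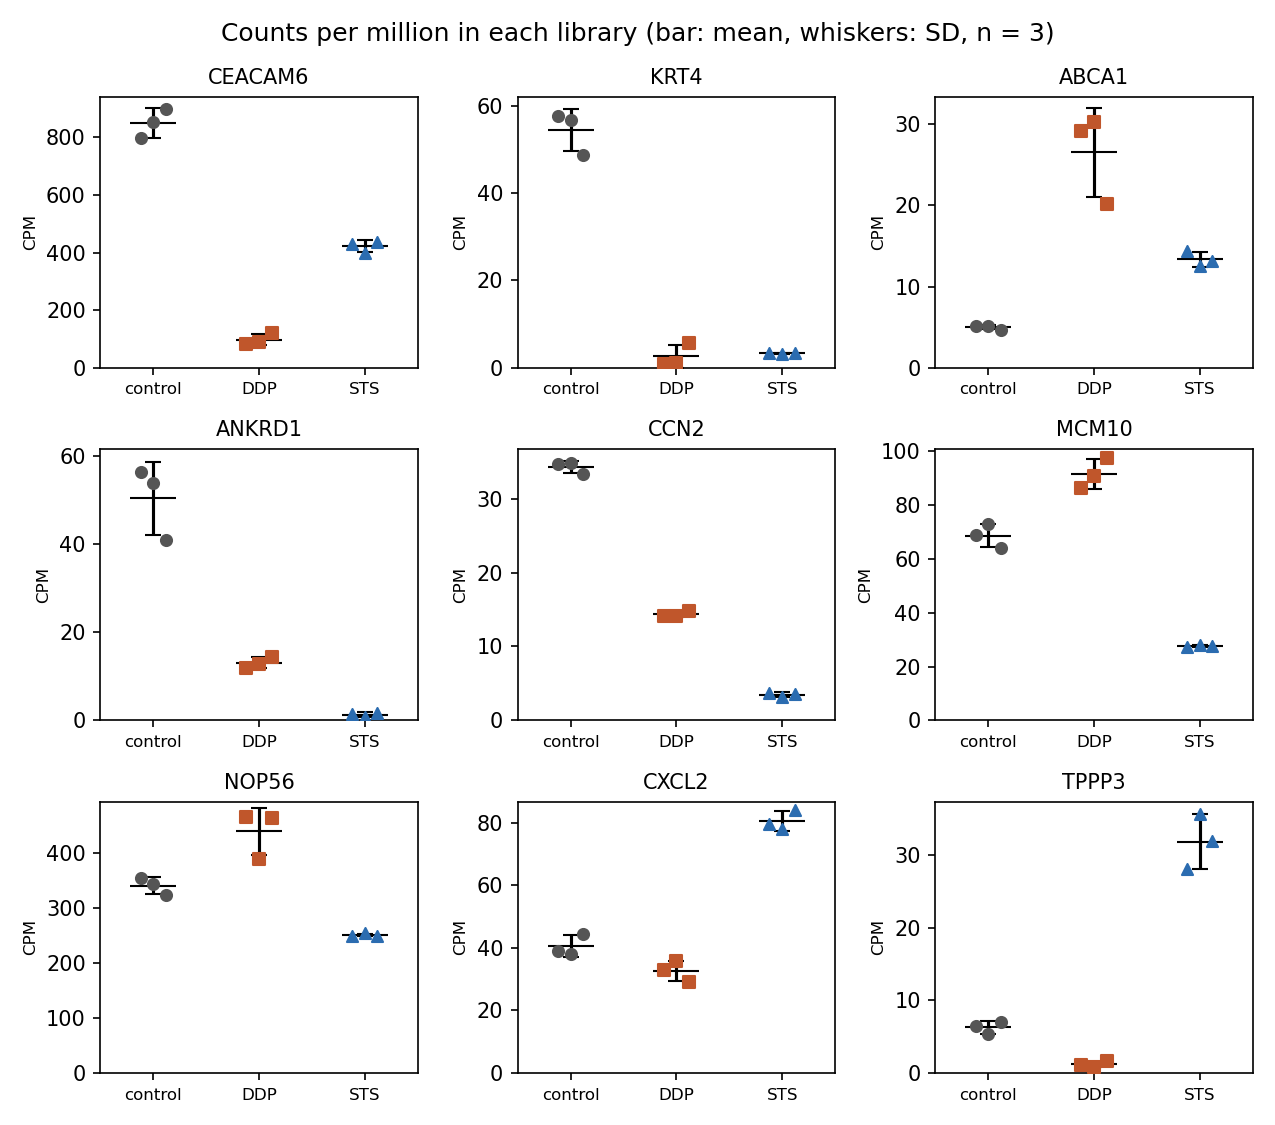
CPM (y axis) of 9 named genes in each library by group (x axis), with points for libraries, a bar for the mean and whiskers for the SD (n = 3). MCM10 lies at 91.4 with DDP_apoEV and 27.6 with STS_apoEV on average, against 68.6 in control.

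Against the same control libraries, 892 genes were called in the same direction with both kinds of vesicle, 410 higher and 482 lower. SLC16A6, BMPER, ABCA1 and ANKRD22 were among those that rose with both, and KRT4, FGG and HMGCS1 among those that fell. Lists drawn independently, with every gene equally likely to be called, would share 193 higher and 237 lower genes. Genes differ in how easily they are called, so an excess over these numbers does not by itself show shared effects. In 20 simulations of unchanged groups against shared controls there was at most 1 shared call. With no effect in either simulated group few genes could be called at all. The simulations therefore do not bound what shared controls add where many genes change. Another 524 genes were called in opposite directions, 255 higher with DDP_apoEV and lower with STS_apoEV and 269 the reverse, where independent lists would give 204 and 224. All 524 also passed the test between the vesicle types. That was nearly assured, since effects called in opposite directions against the same control add up in this difference. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons had a Pearson r of 0.296 (Spearman rho 0.181), and shared controls alone gave a simulated r of 0.50. Their covariance was 0.0946 against a simulated 0.0377, a difference of 0.0569. The 3 control libraries are too few to split, so part of the excess in shared calls may come from the shared controls.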

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

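The tests of depth, of GC content and length, of scaling and of the control libraries in this part, and the fits without single libraries for genes outside the comparison that named them, were chosen after the results they bear on were seen, and the counts over other splits were planned. The lists and genes of the next 2 paragraphs stand here because the effects of the 2 vesicle types against control were called in opposite directions and the difference between them, STS_apoEV minus DDP_apoEV, passed its own test. For genes called in opposite directions a pass in that test was nearly assured, so it adds little to the 2 calls. Groups of 3 libraries are too small for a test of single outlying samples, and no data lay outside the comparisons of the report.

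The DNA replication list (median log2 difference of its genes −0.777) and the ribosome biogenesis list (−0.602) rose with DDP_apoEV and fell with STS_apoEV. Library depth, greatest in DDP_apoEV, was tested by thinning all libraries to the lowest total, and the largest of the 4 camera adjusted p against control was then 2.52e-05. Thinning keeps each gene's expected share of its library, so this bears only on unequal sampling noise and not on biases made before sequencing. Removing each library's trends on GC content and transcript length left the largest at 2.15e-05, so the tables argue against such trends as the whole cause. What stays open is whether the vesicle type, carried-over drug, vesicle dose or cell density set the direction, since each would follow the groups and no sample separates them. With an estimated correlation the DDP_apoEV rise of the DNA replication list was not called (adjusted p = 0.167) and its fall with STS_apoEV was (0.0471), while the ribosome biogenesis list lost its rise (0.167), its fall (0.194) and its difference between the vesicle types (0.115).

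Of the named genes reported here 26 were called in opposite directions, 14 of them higher with DDP_apoEV. Their log2 differences were −3.54 for NPTX1, −2.01 for WWC1, −1.73 for MCM10, −1.60 for AXL, −1.60 for UHRF1, −1.19 for CDC6, −1.14 for MSH6, −1.13 for NOLC1, −0.99 for MCM6, −0.97 for STIP1, −0.86 for DKC1, −0.84 for WDR43, −0.81 for NOP56 and −0.75 for BCL2L1. Those lower with DDP_apoEV and higher with STS_apoEV had differences of 0.71 for CDKN1A, 0.89 for AKR1C1, 1.003 for CTSA, 1.13 for CCL2, 1.29 for MUC13, 1.303 for CXCL2, 1.66 for CXCL3, 3.82 for KLRC2, 4.04 for TCN1, 4.09 for CP, 4.41 for F5 and 4.74 for TPPP3. The largest adjusted p among the 26 differences was 2.66e-05. With each library of a comparison left out in turn, 0 of these 26 genes lost the call with STS_apoEV against control or between the vesicle types, and 9 lost that with DDP_apoEV against control in at least 1 fit. STIP1 lost it whichever library was left out, control replicate 1 (adjusted p = 0.0590), 2 (0.134) or 3 (0.150) or DDP_apoEV replicate 1 (0.115), 2 (0.110) or 3 (0.0701). The call was lost for CDC6 without control replicate 3 (adjusted p = 0.0547), UHRF1 without control replicate 2 (0.0503) and MCM6 without control replicate 3 (0.0964). It was lost for CDKN1A without control replicate 1 (0.0945), control replicate 3 (0.101), DDP_apoEV replicate 1 (0.178) or DDP_apoEV replicate 3 (0.140), and for BCL2L1 without control replicate 2 (0.184), DDP_apoEV replicate 1 (0.106) or DDP_apoEV replicate 2 (0.0764). Among chemokine genes it was lost for CCL2 without control replicate 3 (0.0941), DDP_apoEV replicate 1 (0.0703) or DDP_apoEV replicate 2 (0.113), for CXCL2 without control replicate 3 (0.139), DDP_apoEV replicate 1 (0.05 after rounding, not below the threshold) or DDP_apoEV replicate 3 (0.127), and for CXCL3 without control replicate 3 (0.0891). Leaving out control replicate 2 moved KLRC2 from −2.02 to −1.41 with DDP_apoEV and from 1.80 to 2.40 with STS_apoEV on the log2 scale, and both stayed called.

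A further pattern, in which the effects did not oppose each other, was that the ribosomal protein, mitochondrial-genome and histone lists were called higher in both vesicle groups. All 6 calls were lost with an estimated correlation (adjusted p = 0.540, 0.540 and 0.167 with DDP_apoEV, and 0.714, 0.585 and 0.0802 with STS_apoEV). Removing trends on GC content and transcript length left the largest of the 6 adjusted p at 0.0337. With median-of-ratios factors it was 0.0267, which decides nothing about scaling, since camera compares a list with the other genes and a size factor moves all genes of a library alike. Chance values of the shared control libraries stay open, because without control replicate 1 the mitochondrial list with STS_apoEV had an adjusted p of 0.103, and because 3 controls cannot be split. Camera called none of these lists between the vesicle types. Fry called the histone list higher with STS_apoEV than with DDP_apoEV (adjusted p = 3.24e-04), with 5 of 9 genes higher and 1 lower.

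The splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. The real split gave 2836, 5537 and 6545 genes for DDP_apoEV against control, STS_apoEV against control and the vesicle types against each other, and the highest other split 1, 0 and 1, so 1 of 10 splits was as large each time. For gene lists the real splits gave 15, 21 and 16 and the highest others 9, 10 and 15. Of 100 of the 280 splits of the 9 libraries into 3 groups, only the real one gave as many as 7642 genes differing. The highest other gave 3833, so the share was under 0.05. Such shares concern chance among these libraries only. They cannot exclude differences between cultures, since the labels do not say that the libraries of a group came from separate cultures. For genes called in both against control, 2 of the 100 splits, the real one included, reached 892, a share under 0.05. The other gave 3110, and there the 3 STS_apoEV libraries served as the control against sets mixed from control and DDP_apoEV libraries, a structure of the samples. A correlation of the 2 fold changes as large as 0.296 came from 77 of the 100 splits, with 0.855 the highest other, so chance is not excluded for it. This count could hardly have excluded chance, since shared controls alone gave a simulated r of 0.50. The median of the other splits was 0.5625. The count therefore does not decide whether the 2 effects are alike.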

How the results depend on the processing

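The thinning and the removal of GC and length trends were chosen after the results were seen. Under the alternatives run, the counts of genes and lists stayed within 1.5 times except as follows. A 2-fold minimum left 560, 1130 and 1481 genes in the 3 comparisons and 1540 differing among groups, by its construction. Limma on FPKM called 1624 genes for DDP_apoEV against control with log2(FPKM + 1), 1622 with log2(FPKM + 0.1) and 992 without a filter, where STS_apoEV against control gave 3617 and the 3 groups 4825, and the cause was not tested. These fits covered other sets of genes, 12647 with the FPKM filter and 37966 without it, against 16947 in the main test. With an estimated correlation 0, 2 and 1 lists were called, and with fry, which does not compare a list with other genes, 24, 34 and 30. Fry did not call 3 of the lists that camera called, cytosolic ribosomal proteins with DDP_apoEV (adjusted p = 0.0586) and STS_apoEV (0.117) and mitosis with DDP_apoEV (0.0584). The balance of higher and lower genes lay near even and its majority turned. For STS_apoEV against control it turned with upper-quartile factors (2977 higher and 2596 lower). For DDP_apoEV against control it turned with log2(FPKM + 1) (819 and 805). Between the vesicle types it turned with median-of-ratios factors (3292 and 3429), DESeq2 (3099 and 3272), no filter on counts (3052 and 3231), the 2 groups fitted alone (3255 and 3290), limma on log2(FPKM + 1) (2300 and 2904), log2(FPKM + 0.1) (2280 and 2893) or unfiltered FPKM (2187 and 2463), and without DDP_apoEV replicate 2 (2935 and 3042) or STS_apoEV replicate 1 (2889 and 2967). The 2-fold minimum turned it for STS_apoEV against control (699 and 431). The correlation of fold changes was 0.235 over genes differing among groups. Without single libraries the counts ran from 1841 to 2236, 4621 to 5267, 5856 to 6235 and 6795 to 7251 genes, 13 to 15, 19 to 23 and 15 to 18 lists, 650 to 875 genes called in both, and a correlation of 0.272 to 0.385. Signs turned for values near 0. MKI67 with DDP_apoEV had −0.0035 with upper-quartile factors, −0.00068 with limma-voom and −0.0781 to 0.0580 without single libraries, ACTB with DDP_apoEV −0.0971 to 0.0364, and GAPDH with STS_apoEV 0.0230 with upper-quartile factors and −0.0761 to 0.0320.

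The replicate block gave 2359, 5297, 6429 and 7310 genes, 13, 21 and 16 lists, 796 genes called in both and a correlation of 0.295. The numbers do not pair the libraries, since same-numbered deviations correlated at −0.085 to 0.055 and 2 of 9 libraries correlated best with their own number. With the block BCL2L1 (adjusted p = 0.0505) and the mitosis list (0.0808), both with DDP_apoEV against control, did not pass. Over the 158 values of named genes, called or not, 28 of 948 fell short of the threshold without a library, and with DESeq2 158 of 158 stayed on their side of it. Thinning to equal depth gave 2562, 5489, 6574 and 7561 genes, and removing GC and length trends 15, 23 and 18 lists. At this depth 53 to 61 of 100 simulated 1.5-fold changes were recovered.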

Other observations

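Both tests in this part that offer a hypothesis were chosen after the values were seen. Camera did not call the stemness and immune ligand lists. Fry called the stemness list higher with DDP_apoEV (adjusted p = 0.00827) and STS_apoEV (0.0468), and the immune ligand list likewise (0.00523 and 1.3e-04). The other adjusted p of lists in this paragraph are from camera. Of 11 stemness genes 4 rose and 0 fell with DDP_apoEV (4 rose adjusted over the list alone; adjusted p = 0.107) and 5 rose and 4 fell with STS_apoEV (5 rose and 4 fell adjusted over the list alone; adjusted p = 0.853). Of 12 immune ligand genes 2 rose and 1 fell with DDP_apoEV (2 rose and 3 fell adjusted over the list alone; adjusted p = 0.361) and 7 rose and 1 fell with STS_apoEV (7 rose and 2 fell adjusted over the list alone; adjusted p = 0.0694). With STS_apoEV the stemness list had a median log2 fold change of −0.27 and a mean of 0.10. SOX2, a stem-cell transcription factor gene, rose with both kinds of vesicle (log2 fold changes 1.65 and 1.63). NT5E, which makes immunosuppressive adenosine, rose by 0.93 with DDP_apoEV and 1.11 with STS_apoEV, and the checkpoint ligand gene CD274 rose by 1.24 with STS_apoEV (adjusted p = 0.0202), while the poliovirus receptor gene PVR fell with both, by 0.29 and 1.07. MYC rose by 0.37 with DDP_apoEV and fell by 0.30 with STS_apoEV. These genes were picked after their values were seen. Lists tied to the uptake of dying cells were not called. Of 22 genes for clearance of apoptotic cells 3 rose and 6 fell with DDP_apoEV (3 rose and 6 fell adjusted over the list alone; adjusted p = 0.994) and 5 rose and 5 fell with STS_apoEV (5 rose and 5 fell adjusted over the list alone; adjusted p = 0.984).

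Markers of other cell types were summed per group without a test (SD, n = 3). Stromal markers came to 16.8 ± 1.18, 13.4 ± 1.73 and 13.7 ± 1.88 CPM in control, DDP_apoEV and STS_apoEV. Endothelial markers came to 27.9 ± 2.68, 30.5 ± 4.03 and 36.9 ± 3.50 CPM, of which EGFL7 held 87.8%. Lymphocyte markers came to 1.39 ± 0.562, 1.23 ± 0.246 and 2.01 ± 0.825 CPM, and blood and platelet markers to 2.41 ± 0.848, 3.97 ± 1.22 and 1.52 ± 0.558 CPM.

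A hypothesis is that cisplatin carried over with the vesicles acted on the cells. Platinum damage at an active dose raises p53 targets, and of 25 such genes 1 rose and 4 fell with DDP_apoEV (1 rose and 4 fell adjusted over the list alone; median log2 fold change −0.07; camera adjusted p = 0.178). TNFRSF10B rose and GDF15, TP53INP1, CDKN1A and BTG2 fell. Camera called the list in neither direction, while fry, which does not compare a list with other genes, called it lower (adjusted p = 0.00827). A dose too low to raise these genes, or a response ended by 96 h, could not be excluded. A like test for staurosporine was not made.

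A second hypothesis is that lipid taken up with the vesicles may have lowered cholesterol synthesis genes, of which 15 of 25 fell with DDP_apoEV and 14 fell and 1 rose with STS_apoEV (18 fell, and 14 fell and 1 rose, adjusted over the list alone). Both list calls were lost with an estimated correlation (adjusted p = 0.201 and adjusted p = 0.266). Sterol loading should raise efflux genes driven by LXR. ABCA1 rose 5.28-fold with DDP_apoEV and by 1.41 on the log2 scale with STS_apoEV, but of 12 efflux and LXR target genes only 2 rose with DDP_apoEV (4 rose and 1 fell adjusted over the list alone) and 3 rose and 2 fell with STS_apoEV (3 rose and 2 fell adjusted over the list alone). Fry called this list higher with DDP_apoEV (adjusted p = 0.0382) but not with STS_apoEV (0.481). The larger of the camera adjusted p was 0.853, which leaves the hypothesis undecided.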
